A study of Mus musculus with 41 samples.

How the data were processed

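RNA was measured in 11 bulk libraries and 26 single cells of fetal mouse lung. The 4 tables deposited by the authors hold expected counts per gene symbol, as the values show, since 5.35 to 9.21% of the values in each bulk library were not whole. The ribosomal RNA precursor Rn45s held 0.902 to 9.83% of bulk counts. Per the submitters' processing notes, the genome build was mm10, and Trim Galore, Bowtie2, MACS2, HOMER, TopHat2 and Partek were used, with no version or role stated; the counting rule and its use of strand are not given in the sources used here. Fractional counts can come from reads shared between genes, so near-identical copies and overlapping genes were treated as uncertain. Each table held the same 24371 genes, of which 24240 matched the GRCm38.p6 gene table that gave the positions. The labels' protocols describe CD106 selection, after depletion of CD45, CD31 and CD309, for the accessibility samples, and not for the RNA fractions. The column of the dexamethasone CD106+ table carries a code that no label holds, and it was assigned to that group because no other sample's description names the table.

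Expected counts were rounded to whole numbers. Genes were kept by filterByExpr, libraries scaled by TMM, and groups compared by edgeR's quasi-likelihood test with robust estimation and Benjamini-Hochberg adjustment at 0.05 (R 4.3.3, edgeR 4.0.16, limma 3.58.1), with only the groups compared in each fit. Means in these comparisons and the values of pools far from the rest are CPM on TMM-scaled library sizes, and levels per library or over cells are CPM of total counts. Lists of genes (29, of pathways and cell types) were fixed before the data were examined and tested with camera at a preset correlation of 0.01 where 5 or more genes were tested, and again with an estimated correlation and with fry. Medians of lists carry a 95% interval from order statistics over genes, which are not independent. Genes named are the 8 largest rises and falls among genes past the threshold with mean logCPM of 3 or more and no overlap between groups, up to 4 members of each pathway list and 2 of each cell type list by smallest p, and Nr3c1, Fkbp5, Tsc22d3, Per1, Vcam1, Ptprc, Pecam1, Kdr and Twist2; for untested comparisons, the 8 largest ratios each way at 20 CPM or more, those 9 genes and the members named for mesenchyme. Xist, Col2a1, Epcam, Tagln and, in the treated CD106+ library, Col1a1 and Scgb1a1 fall outside this rule and were chosen after their values were seen. Twist2 was too low to test.

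The dexamethasone CD106+ library and the single cells had 1 sample per group. They were described by log2 ratios of CPM plus a pseudocount of 1, and list medians were placed among 10000 random lists matched on expression in 20 bins. No clusters were made of the 26 cells and no doublet caller was run. Folds against a group with no counts are bounds at 3 counts. The tests were checked on simulated counts with 200 changed genes: edgeR recovered 14% of changes of 1 and 54% of changes of 2 on the log2 scale at the size of the mesenchyme comparison, over 10871 genes, and 17% and 73% at that of the CD106 comparison, over 12080 genes. False calls numbered 4 of 72 and 5 of 95. The real comparisons called more genes than were planted, 306 and 1239, so recovery there may differ. No replicate pair agreed within sampling noise, with chi-square per degree of freedom of 9.94 to 40.4. Alternatives were other scalings, filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, an edgeR fit of the dexamethasone CD106+ library with both CD106 fractions, other pseudocounts and, added after seeing the data, removal of sex chromosome genes, of Rn45s, of cells with Pecam1 above 100 CPM and of Vcam1 from its lists, and covariates for Xist and chondrocyte markers. Plots were made with matplotlib 3.10.9.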

Results

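The samples came from lungs of fetal mice. Dexamethasone is a synthetic glucocorticoid that binds the receptor encoded by Nr3c1. In the first set, pregnant dams received 1 mg/kg dexamethasone or saline at E18.5, and 2 hours later Twist2Cre-labelled mesenchyme was sorted from fetal lungs pooled by genotype, giving 4 dexamethasone and 2 saline pools of about 1670900 to 4224240 counts each. In the second, cells carrying CD106, the surface protein encoded by Vcam1, were set against cells lacking it at E18.5, with 2 libraries per fraction of about 4987180 to 7133940 counts, beside 1 CD106+ library from dexamethasone treatment at 1 mg/kg with about 3790540 counts. In the third, 26 cells were profiled individually 24 hours after injection at E17.5, 15 of them after 2 mg/kg dexamethasone and 11 after saline. Another 4 chromatin accessibility samples of CD106+ cells were not analysed here. The labels do not say that the pools or fractions came from separate litters, so p-values measure the spread between these samples, which may be technical in part. Errors are SD unless named otherwise, gene positions are in GRCm38, and levels are CPM, counts scaled to a common library total.

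Known glucocorticoid target genes rose in sorted mesenchyme 2 hours after injection. Glul, which encodes glutamine synthetase (chromosome 1, 153899929 to 153909723), stood at 1616 ± 339 against 207 ± 18.8 CPM (n = 4 and 2; log2 fold change 2.96, SE 0.27, adjusted p = 1.5e-05 by edgeR). Errfi1, an inhibitor of EGF receptor signalling (chromosome 4, 150853796 to 150868889), stood at 1030.0 ± 63.4 against 184 ± 23.8 CPM (log2 fold change 2.48, SE 0.23, adjusted p = 1.5e-05 by edgeR). Pdk4, a kinase that restrains pyruvate oxidation, rose by 2.68 on the log2 scale, Fkbp5, a chaperone partner of the receptor, by 2.59, and Tsc22d3, which encodes GILZ, by 1.77 (edgeR adjusted p = 3.6e-05, 4.6e-05 and 9.9e-04). In the other direction, the growth-factor-induced regulator Egr1 (chromosome 18, 34861207 to 34864956) stood at 163 ± 33.3 against 668 ± 108 CPM (log2 fold change -2.04, edgeR adjusted p = 3.6e-05) and the growth factor Fgf18 (chromosome 11, 33116970 to 33147400) at 8.68 ± 3.59 against 57.3 ± 31.9 CPM (log2 fold change -2.72, edgeR adjusted p = 0.0022). Fgf18 lost its call without saline pool 2 (adjusted p = 0.12), and the other 6 kept theirs whichever pool was left out. Fits without a saline pool hold 1 saline pool, assumed to vary like the dexamethasone pools.

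Of 11356 genes tested, 306 changed at an edgeR adjusted p under 0.05, 222 upwards and 84 downwards, and 1571 had an unadjusted p under 0.05. The groups also differed in sex. Both saline pools read as female, with Xist at 33133 and 20879.6 CPM and Ddx3y at 1.20 and 0 CPM. Dexamethasone pools 1, 3 and 4 read as male, with Xist at 374, 12.6 and 6.59 CPM, and pool 2 as mixed, with Xist at 11111 and Ddx3y at 74.4 CPM. The Y-linked genes Ddx3y, Kdm5d and Uty led the rises, at 124 ± 44.6 against 0.61 ± 0.862 CPM, 122 ± 58.4 against 0.915 ± 1.29 CPM and 92.8 ± 34.5 against 0.803 ± 0.589 CPM. Of the 306 genes, 18 lie on X or Y, and 284 genes changed when genes on those chromosomes were left out, an alternative chosen after seeing the data. With the Xist level as a covariate, 0 genes passed by edgeR and 746 had an unadjusted p under 0.05. The median fold of the raised autosomal genes went from 1.60 to 1.72 on the log2 scale and of the lowered from -1.70 to -1.62, all with the same sign, while the median SE grew from 0.29 to 0.64 and from 0.36 to 0.92. These genes were called in the same pools, so their folds and signs were in part fixed by that choice. The cartilage collagen Col2a1 was also uneven, at 1090.4 and 403 CPM in saline against 6.15, 26.9, 247 and 40.4 CPM under dexamethasone, and 44 genes passed with the mean chondrocyte marker level as a covariate, where these medians went to 1.37 and -1.52 and their SE to 0.40 and 0.61.

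**Figure D1:**
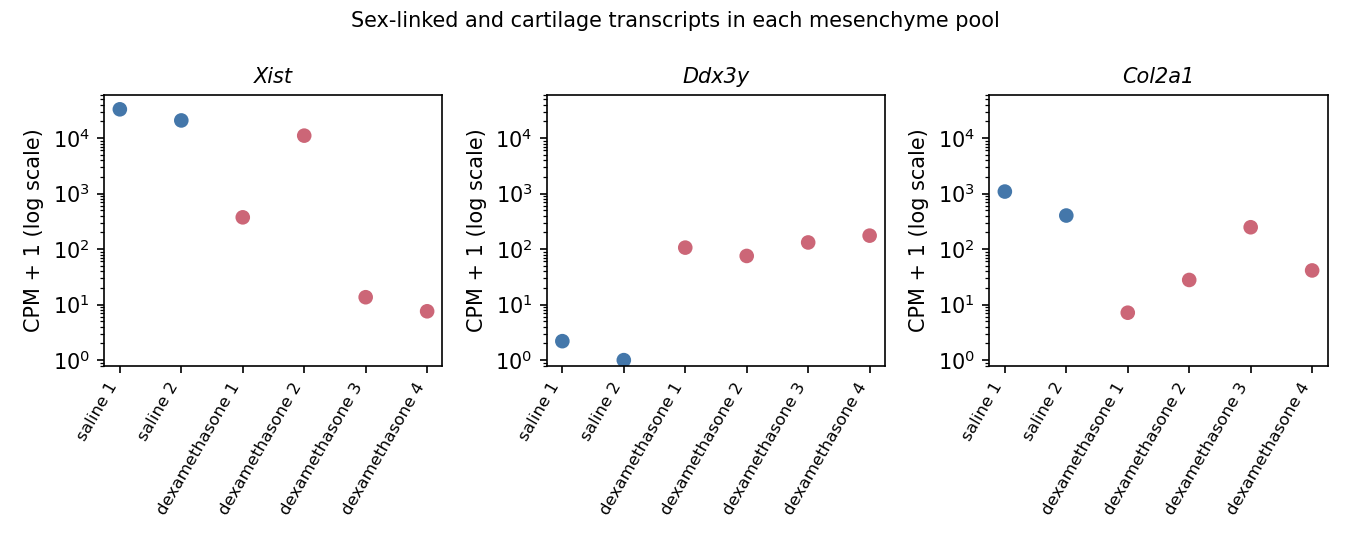
CPM plus 1, on a log axis, of Xist, Ddx3y and Col2a1 in each mesenchyme pool, saline in blue and dexamethasone in red. Xist lies at 20879.6 CPM or more in both saline pools and at 374 CPM or less in 3 of the 4 dexamethasone pools.

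Of the glucocorticoid targets, 17 of 29 tested rose, 0 fell and 12 did not pass, and 23 rose when adjusted over the list alone. The list median was 1.73 on the log2 scale (camera adjusted p = 5.5e-43, and adjusted p = 0.036 with an estimated correlation). The clock and glucocorticoid gene Per1 did not pass, at 86.1 ± 34.4 against 64.2 ± 6.33 CPM (edgeR adjusted p = 0.64), nor did the receptor gene Nr3c1, at 227 ± 33.5 against 352 ± 3.80 CPM (edgeR adjusted p = 0.14). Of 9 receptor and steroid handling genes, 2 rose, and adjusted over the list alone 2 rose and 1 fell. The 2 were Hsd11b1, whose enzyme regenerates active glucocorticoid, at 279 ± 53.1 against 121 ± 43.9 CPM, and the corepressor Nrip1, at 313 ± 68.9 against 128 ± 38.2 CPM. Among lipid handling genes, the triglyceride lipase gene Pnpla2 and the cholesterol exporter Abca1 rose, with log2 fold changes of 2.96 and 1.01. The protease Adamts1 rose by 1.13 and the chaperone Dnaja1 by 0.99, each the only gene past the threshold among 15 matrix remodelling and 12 heat shock genes (2 rose and 0 fell, and 1 rose and 0 fell adjusted over the list alone). Lists with 1 rise and 1 fall were the 21 TGF-beta and BMP genes, where the coreceptor Tgfbr3 rose by 1.35 and Id3 fell, the 18 vascular growth factor genes, where Angpt1 rose by 0.95 and Cxcl12 fell, and the 12 myofibroblast markers, where the lysophospholipase Enpp2 rose by 1.43 and Fgf18 fell. Adjusted over the list alone, rises and falls numbered 1 and 2, 1 and 2, and 2 and 4 in these 3 lists. Counts of Dnaja1 and Enpp2 were fractional in 100% of the pools, so they may hold reads shared with other genes and are uncertain. The epithelial sodium channel gene Scnn1a and Fam107a were among the 8 largest rises, with log2 fold changes of 3.54 and 3.37. Fam107a kept its call whichever pool was left out, with log2 fold changes that ran from 2.80 to 4.73. Nrip1 lost it without saline pool 1 (adjusted p = 0.14), Scnn1a without saline pool 1 (adjusted p = 0.062) and Tgfbr3 without saline pool 2 (adjusted p = 0.054). For Hsd11b1 it was lost without saline pool 1 or dexamethasone pool 1 or 4 (adjusted p of 0.056 to 0.22), and for Pnpla2 without saline pool 2 or dexamethasone pool 1 or 4 (adjusted p of 0.054 to 0.2). The Abca1 call was lost without saline pool 2 or dexamethasone pool 1 or 4 (adjusted p of 0.058 to 0.19), and the Adamts1 call without saline pool 1 or 2 or dexamethasone pool 1 (adjusted p of 0.057 to 0.15). Dnaja1 lost its call without saline pool 1 or dexamethasone pool 1, 2 or 4 (adjusted p of 0.063 to 0.28), and Enpp2 without saline pool 2 or dexamethasone pool 1, 2 or 4 (adjusted p of 0.06 to 0.16). Angpt1 lost its call without saline pool 1 or 2 or dexamethasone pool 1, 2 or 4 (adjusted p of 0.098 to 0.22).

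**Figure D2:**
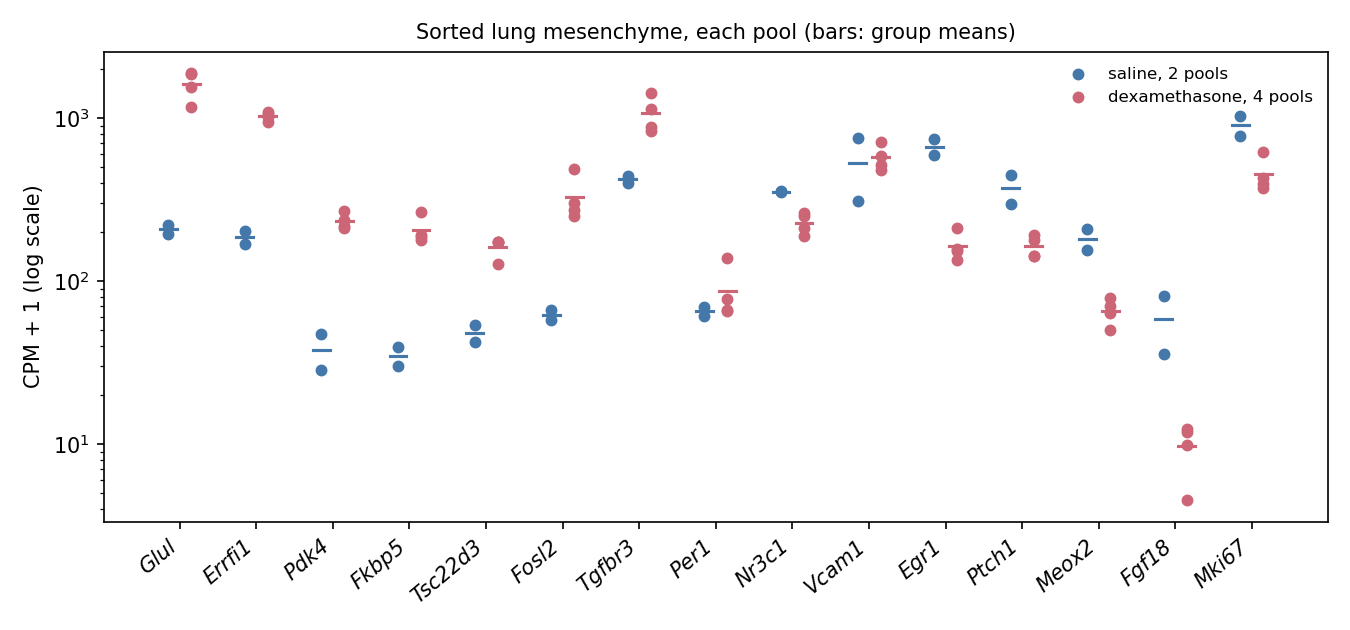
Normalised CPM plus 1, on a log axis, of 15 genes in each mesenchyme pool, saline in blue (n = 2) and dexamethasone in red (n = 4), with bars at the group means. Glul has means of 207 CPM in saline and 1616 CPM under dexamethasone, and Vcam1 has 531 and 574 CPM.

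Signalling and transcription factor genes were among those that fell. Ptch1, the hedgehog receptor and target, stood at 163 ± 25.8 against 369 ± 106 CPM (log2 fold change -1.18), and with Fgf18 it made 2 of 22 hedgehog and FGF genes that fell, with 0 rising (2 rose and 4 fell adjusted over the list alone). The Wnt modulator Sfrp2 fell by 1.91 on the log2 scale as 1 of 21 Wnt genes (3 fell adjusted over the list alone), and the BMP-responsive Id3 fell by 1.54. The homeobox gene Meox2, a matrix fibroblast marker, stood at 64.7 ± 12.3 against 181 ± 38.5 CPM (log2 fold change -1.48, edgeR adjusted p = 0.0027), and 14 of the 15 markers of that cell type did not pass. The chemokine Cxcl12 fell by 1.26, the only 1 of 10 NF-kB and inflammatory genes to pass. Of 31 collagen and matrix genes, Fbln5 and Fbln2 fell, by 0.96 and 1.85, and 29 did not pass (2 rose and 2 fell adjusted over the list alone). Nov, Tbx20, Muc5b and Ston2 were among the 8 largest falls, with log2 fold changes of -2.65, -2.26, -3.02 and -3.13. Nov kept its call whichever pool was left out, and Ston2 lost it without saline pool 1 (adjusted p = 0.32). Without saline pool 2, calls were lost for Ptch1, Fgf18, Sfrp2, Meox2 and Muc5b (adjusted p = 0.16, 0.12, 0.12, 0.06 and 0.2). Cxcl12 lost its call without saline pool 2 or dexamethasone pool 1 (adjusted p of 0.051 to 0.18), and Id3 without saline pool 1 or 2 or dexamethasone pool 1 (adjusted p of 0.058 to 0.1). Tbx20 lost its call without saline pool 1 or 2 or dexamethasone pool 2 (adjusted p of 0.051 to 0.1). Fbln5 lost its call without saline pool 2 or dexamethasone pool 1, 2 or 3 (adjusted p of 0.053 to 0.16), and Fbln2 without saline pool 2 or dexamethasone pool 1, 2 or 4 (adjusted p of 0.099 to 0.37).

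As lists, 6 others passed camera downwards, and none of them passed with an estimated correlation. By fry the smooth muscle and immediate early lists passed downwards (fry adjusted p = 0.0079 and 0.016), and the rest did not. Of 16 immediate early genes, Egr1, Btg2 and Nr4a1 fell and Fosl2 rose by 2.43 (2 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.032, and adjusted p = 0.43 with an estimated correlation). Of 29 cell cycle genes, Mki67 fell, at 453 ± 114 against 903 ± 174 CPM, as did Mcm5, at 6.17 ± 1.97 against 23.5 ± 6.56 CPM, 3 fell adjusted over the list alone, and the list median was -0.91 (camera adjusted p = 2.0e-06, and adjusted p = 0.55 with an estimated correlation). The other 4 lists had 0 members past the threshold over all genes. The 12 smooth muscle markers had a median of -0.50, and 1 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.42 with an estimated correlation). The 7 chondrocyte markers had a median of -2.79 (camera adjusted p = 9.3e-05, and adjusted p = 0.55 with an estimated correlation). Of 8 erythroid genes, 2 fell adjusted over the list alone (median -1.07, camera adjusted p = 0.029, and adjusted p = 0.61 with an estimated correlation). Of 6 cardiac and skeletal muscle genes, 2 fell adjusted over the list alone (median -0.73, camera adjusted p = 0.029, and adjusted p = 0.55 with an estimated correlation). The chondrocyte list kept its call whichever pool was left out. The cell cycle list lost it without saline pool 2 (adjusted p = 0.67), with a median there of 0.076. The immediate early list lost it without saline pool 2 or dexamethasone pool 1 or 2 (adjusted p of 0.058 to 0.12), and the smooth muscle list without saline pool 2 or dexamethasone pool 3 (adjusted p of 0.058 to 0.11). For cardiac and skeletal muscle genes it was lost without saline pool 2 or dexamethasone pool 1 or 3 (adjusted p of 0.058 to 0.19). The erythroid list lost it without saline pool 1 or dexamethasone pool 1 or 3 (adjusted p of 0.091 to 0.42), with a median of 0.80 without saline pool 1. The circadian, lipofibroblast, pericyte, mesothelial, adventitial, endothelial and immune lists had 0 members past the threshold, and the epithelial list had 1, Hopx, with a log2 fold change of 2.85. Vcam1 stood at 574 ± 101 against 531 ± 317 CPM (edgeR adjusted p = 0.93), and the endothelial genes Pecam1 and Kdr and the leukocyte gene Ptprc stood at means of 14.4, 7.86 and 3.82 CPM under dexamethasone and 9.58, 8.32 and 3.35 CPM in saline. Of the 45 named genes that passed, 14 kept their call whichever pool was left out. These include the Y-linked Ddx3y, Kdm5d and Uty, whose rise goes with pup sex. They also include Glul, Errfi1, Pdk4, Fkbp5, Fosl2, Egr1 and Tsc22d3, the last on X and so outside the autosomal test of sex. Hopx lost its call without saline pool 2 (adjusted p = 0.085), and Btg2 without saline pool 1 or 2 (adjusted p of 0.07 to 0.074). Nr4a1 lost its call without saline pool 1 or dexamethasone pool 2 or 4 (adjusted p of 0.06 to 0.32). Mki67 lost its call without saline pool 2 or dexamethasone pool 1, 2 or 4 (adjusted p of 0.068 to 0.22), and Mcm5 without saline pool 1 or 2 or dexamethasone pool 1, 2 or 4 (adjusted p of 0.084 to 0.31). The count of 306 fell to 193 without saline pool 1, 179 without dexamethasone pool 1 and 186 without dexamethasone pool 4.

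**Figure D3:**
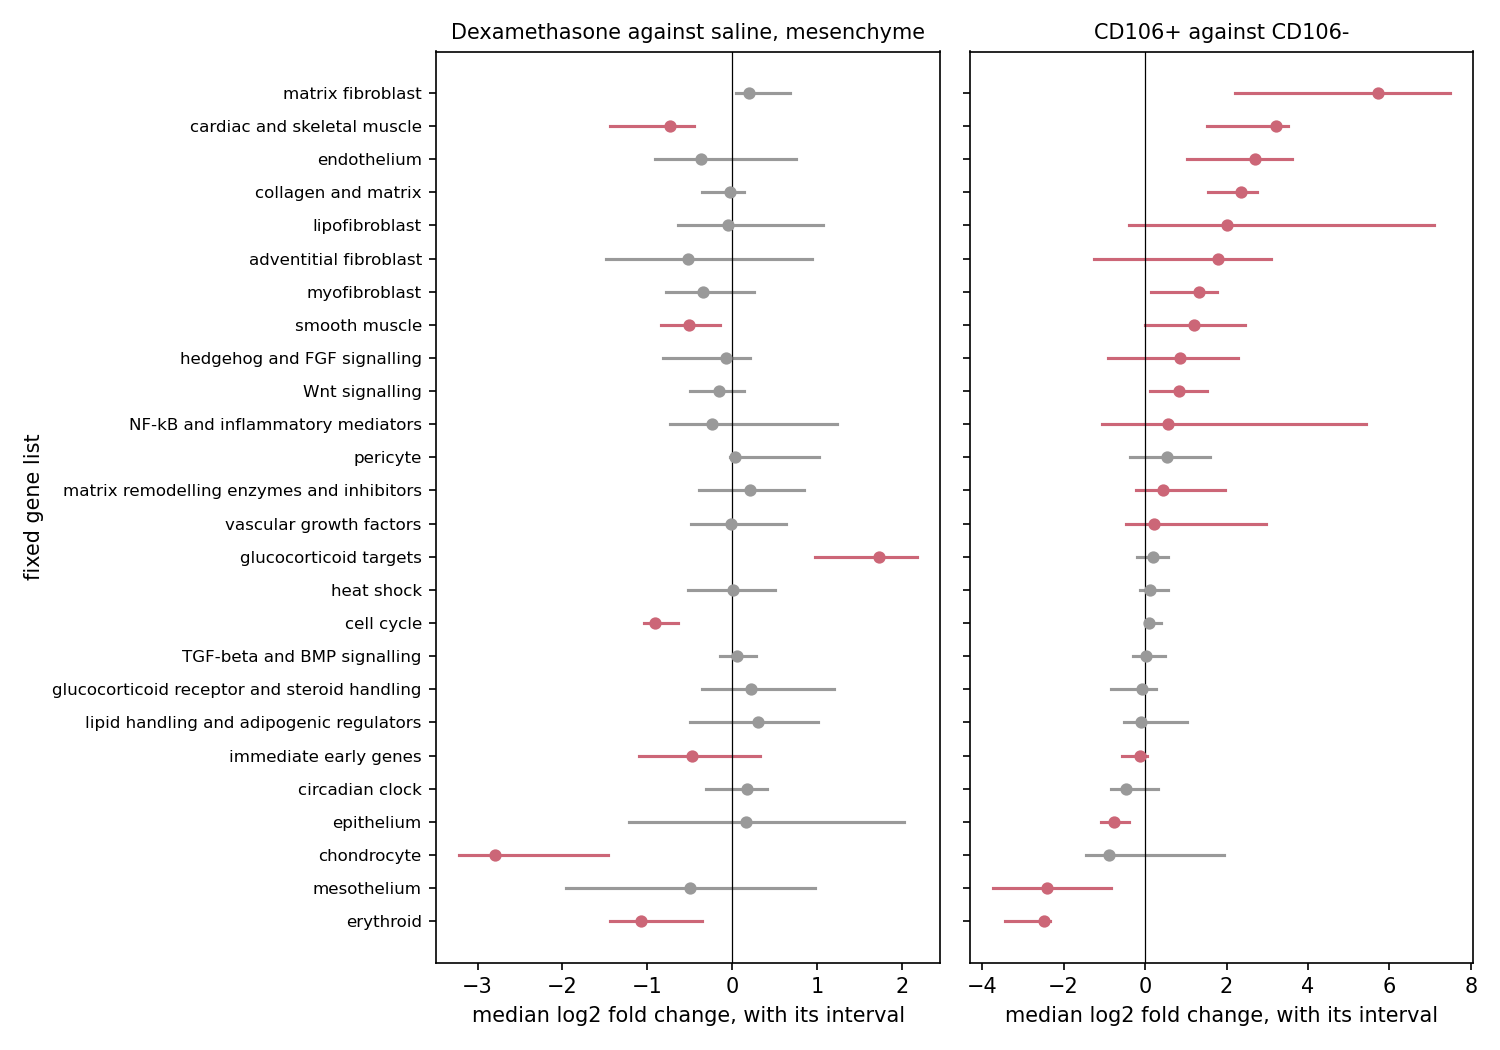
Median log2 fold change of each fixed gene list tested in both comparisons, with the 95% interval of the median over its genes, for dexamethasone against saline in mesenchyme (left) and for CD106+ against CD106- cells (right). Red marks lists past a camera adjusted p of 0.05, and the glucocorticoid targets have medians of 1.73 and 0.20, the second turning to -0.15 without CD106+ library 2.

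The second comparison asked what the CD106+ fraction expressed relative to the CD106- fraction. Vcam1 itself (chromosome 3, 116110020 to 116129688) stood at 609 ± 49.4 against 2.23 ± 1.27 CPM (n = 2 and 2; log2 fold change 8.06, SE 0.43, adjusted p = 3.2e-12 by edgeR). Matrix fibroblast markers stood out in the positive fraction, with 12 of 14 higher (13 adjusted over the list alone; camera adjusted p = 9.4e-57, and adjusted p = 0.31 with an estimated correlation). Vcam1 is 1 of these markers and its product defined the sort, and without it 11 of 13 were higher (camera adjusted p = 2.2e-46, and adjusted p = 0.31 with an estimated correlation). Fgf10, a growth factor of the distal lung (chromosome 13, 118714699 to 118792573), stood at 96.2 ± 16.7 against 1.44 ± 0.424 CPM, Meox2 (chromosome 12, 37108540 to 37179534) at 163 ± 44.8 against 1.16 ± 0.827 CPM and Wnt2 at 30.1 ± 21.1 against 0.0951 ± 0.135 CPM (edgeR adjusted p = 2.0e-10, 5.9e-11 and 1.2e-06). Matrix genes were higher in 23 of 31 cases, including Mfap4, Col6a1 and Col1a1 with log2 fold changes of 6.11, 3.67 and 2.85 (23 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.5e-34, and adjusted p = 0.31 with an estimated correlation). In the negative fraction, 5 of 10 mesothelial markers were higher (8 adjusted over the list alone; camera adjusted p = 8.8e-09, and adjusted p = 0.31 with an estimated correlation), among them the retinoic acid enzyme Aldh1a2, at 47.6 ± 0.615 against 6.15 ± 0.16 CPM in CD106+ cells.

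By edgeR, 1239 of 12364 genes differed at an adjusted p under 0.05, 825 higher and 414 lower in CD106+ cells. The share of calls that was higher, 66.6%, ran from 52.0% to 88.5% with a library left out, so the split rests on single libraries. The same threshold on each list by camera passed 17 of 27 lists, and 0 with an estimated correlation or by fry. The NF-kB and inflammatory list, which also holds Vcam1, lost its call without that gene, going from a camera adjusted p of 0.001 to 0.23. Signalling genes higher in the positive fraction included the vascular ligands Figf and Angpt1, with log2 fold changes of 7.51 and 4.61, the BMP modulator Bmper at 6.67, the Wnt modulator Sfrp1 at 3.50 and the hedgehog effector Gli1 at 3.76. By group, 7 of 20 Wnt genes were higher and 0 lower (8 higher adjusted over the list alone, camera adjusted p = 1.2e-05, and adjusted p = 0.32 with an estimated correlation). Of hedgehog and FGF genes, 8 of 22 were higher and 6 lower (12 and 6 adjusted over the list alone, camera adjusted p = 7.7e-04, and adjusted p = 0.32 with an estimated correlation). Of 17 vascular growth factor genes, 5 were higher and 2 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.0053, and adjusted p = 0.32 with an estimated correlation). Chemokines Ccl11 and Cxcl12 were higher, with log2 fold changes of 5.42 and 2.96, and the alarmin Il33 lower, at -1.45, a call lost without CD106- library 1 or 2 (adjusted p of 0.087 to 0.15). Of 30 glucocorticoid targets, 3 were higher and 2 lower (median 0.20, camera adjusted p = 0.47; the median turned to -0.15 without CD106+ library 2), and Hsd11b1 stood at 29.8 ± 25.0 against 0.381 ± 0.538 CPM. Pcdhac2, 6030408B16Rik and Cass4 had no count in either CD106- library, which makes them at least 181-fold, 105-fold and 77.2-fold higher against a floor of 3 counts over the group. Pcdhac2 shares exons with other protocadherin genes and its counts were uncertain for that reason.

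Both fractions held transcripts of other cell types. Cardiac muscle genes were uneven between CD106+ libraries 1 and 2, with Actc1 at 580 and 32.5 CPM and Tnnt2 at 246 and 10.2 CPM. In the same 2 libraries the plasma protein genes Afp and Alb stood at 109 and 238 CPM and at 269.9 and 621 CPM. Epcam, an epithelial adhesion gene, stood at 205 and 198 CPM in CD106+ and 492 and 341 CPM in CD106- libraries, and 7 of 17 epithelial markers were lower in CD106+ cells, including the surfactant gene Sftpb and Lamp3, with log2 fold changes of -1.28 and -1.29. Sftpb lost its call without CD106- library 1 or 2 (adjusted p of 0.067 to 0.16) and Lamp3 without CD106- library 1 or 2 (adjusted p of 0.087 to 0.17). Endothelial markers were higher in the positive fraction in 6 of 11 cases, with Pecam1 at 19.2 ± 5.29 against 2.42 ± 1.95 CPM, a call lost without CD106- library 2 (adjusted p = 0.062). All 7 erythroid genes tested were lower, and Hba-a1 lost its call without CD106- library 2 (adjusted p = 0.055) and Hba-a2 without CD106- library 2 (adjusted p = 0.11). Hba-a1 and Hba-a2 were near-identical copies whose reads could not be split with certainty. With an estimated correlation 0 of the 27 lists passed and 4 had an unadjusted p under 0.05, and fry passed 0 with 13 at an unadjusted p under 0.05. Among lists past camera the estimated-correlation adjusted p was 0.31 for the epithelial, 0.32 for the endothelial and 0.32 for the erythroid list. The cardiac and skeletal muscle list lost its camera call without CD106- library 2 or CD106+ library 1 (adjusted p of 0.085 to 0.79), and the immediate early list without CD106- library 2 or CD106+ library 1 (adjusted p of 0.083 to 0.089). The smooth muscle list lost it without CD106- library 1 (adjusted p = 0.065). The count of 1239 fell to 546 and 686 without CD106- library 1 and 2 and rose to 2756 without CD106+ library 1.

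Genes that changed in mesenchyme were then looked up between the CD106 fractions, which share no library with the mesenchyme set. Genes on X or Y, 18 of the 306, were not removed beforehand, and their change may follow pup sex. Of 211 raised genes tested there, 47 were higher in CD106+ cells, 11 lower and 153 did not pass, where the shares over all genes give 14.1 and 7.07 (median 0.14, camera adjusted p = 8.7e-04). Of 70 lowered genes, 15 were higher, 4 lower and 51 did not pass, where those shares give 4.67 and 2.34 (median 0.020, camera adjusted p = 8.7e-04). Both sets lost their call with an estimated correlation (adjusted p = 0.23 for each). The shares cover all genes tested between the fractions, not only those expressed in mesenchyme. Raised and lowered genes both exceeded them upwards. A link to the dexamethasone response therefore cannot be told apart from mesenchymal expression as such. Abca1, Adamts1, Angpt1 and Hsd11b1 were raised by dexamethasone and higher in CD106+ cells, while Meox2 and Cxcl12 were lowered by dexamethasone and higher in CD106+ cells. In the CD106 fractions the Abca1 call was lost without CD106- library 1 (adjusted p = 0.066) and the Adamts1 call without CD106- library 1 (adjusted p = 0.28).

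In the CD106+ library from dexamethasone treatment, glucocorticoid targets were at higher levels than in the untreated CD106+ libraries. Errfi1 stood at 1513 against 295 and 272 CPM, Glul at 289 against 79.6 and 96.3 CPM, Fkbp5 at 49.6 against 12.6 and 35.5 CPM and Tsc22d3 at 70.7 against 32.9 and 35.7 CPM, the first value in each case from the treated library. Of 30 targets, 22 were 2-fold or more above the untreated mean and 0 lay at 0.5-fold or less (median 1.76, above all 10000 random lists matched on expression, which spanned -0.54 to 0.14 for 95% of draws). Immediate early genes were higher too, with 13 of 23 at 2-fold or more and 0 at 0.5-fold or less (median 1.33, above all random lists), although Egr1 lay lower, at 1041 against 2065 and 1789 CPM. In mesenchyme the immediate early median was -0.47. The NF-kB, immune and endothelial lists described next also lay above all random lists, so that place was not particular to the glucocorticoid targets. Of 12 heat shock genes, 5 were at 2-fold or more and 0 at 0.5-fold or less, with a median of 0.55 whose interval spans 0 (-0.13 to 1.73). Cell cycle genes lay lower, with 27 of 30 at 0.5-fold or less and Mki67 at 985 against 3276 and 2215 CPM. This was 1 library, in a table of its own whose column code matched no sample title, so the values have no replicate check.

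The same library also differed in cell type markers. All 15 endothelial markers were 2-fold or more above the untreated mean (median 3.80), with Pecam1 at 508 against 22.1 and 16.54 CPM, Kdr at 238 against 11.8 and 12.9 CPM and the lymphatic marker Lyve1 at 648 against 18.8 and 7.71 CPM. Immune markers had a median of 2.19 (0.069 to 2.96) and erythroid genes 1.80, with an interval that spans 0 (-0.47 to 2.49). NF-kB and inflammatory genes had a median of 2.11 (1.36 to 3.03), with Ptgs2 at 176 against 1.60 and 1.82 CPM. Epithelial markers went both ways, with 6 of 17 at 0.5-fold or less and 2 at 2-fold or more (median -0.33, percentile 26.3), Epcam at 27.4 against 205 and 198 CPM and the club cell gene Scgb1a1 at 210.3 against 4.41 and 4.77 CPM. Lower were the plasma protein genes Afp, at 0.264 against 109 and 238 CPM, and Alb, at 5.01 against 269.9 and 621 CPM. Cyp1a1, a target of the aryl hydrocarbon receptor, had the largest ratio, at 139.6 CPM (exact Poisson interval 128 to 152) against 0 and 0.140 CPM, an interval that covers counting error only. Vcam1 stood at 268 against 551 and 687 CPM, Fgf10 at 80.5 against 81.0 and 115 CPM and Col1a1 at 759 against 574 and 952 CPM. Of 222 genes raised in mesenchyme, 168 lay on the same side here (75.7%, exact binomial interval 69.5% to 81.2%, random lists 39.6%), against 37 of 78 lowered genes (47.4%, 36.01% to 59.1%, random lists 59.0%). The binomial intervals treat genes as independent, which they are not. Genes on X or Y were not removed from either set. Random lists were matched on expression and not on cell type, so treatment and cell make-up are not separated.

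**Figure D4:**
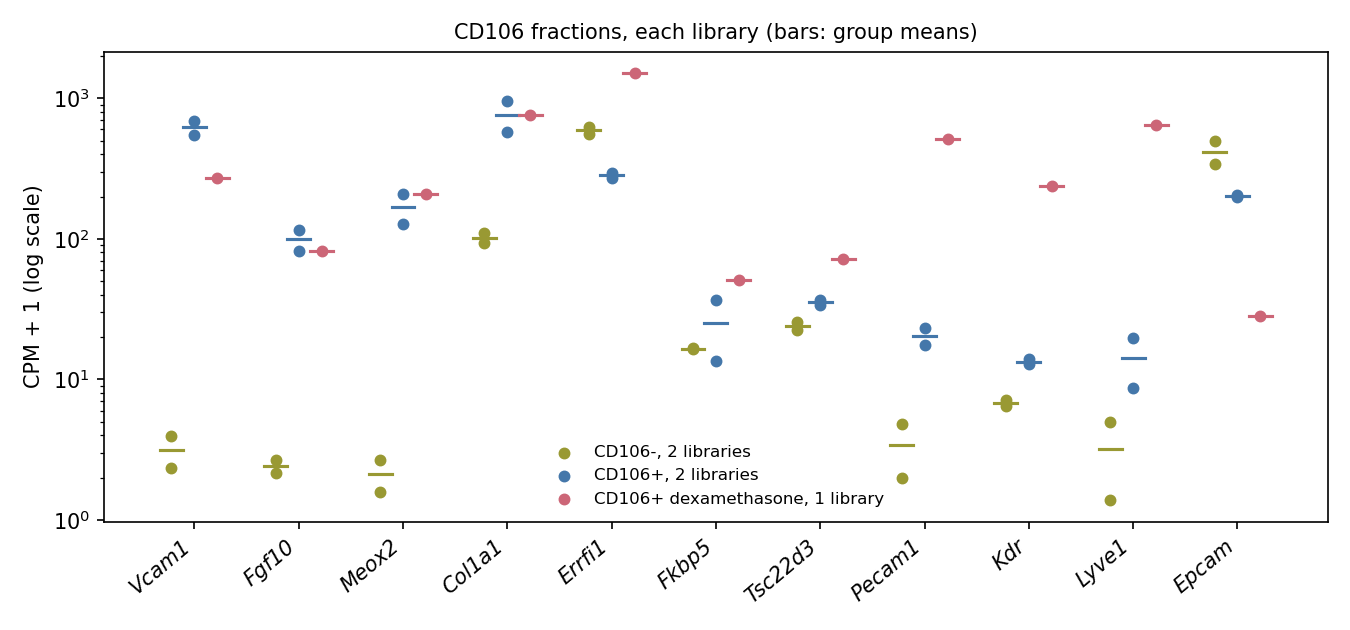
CPM plus 1, on a log axis and scaled to total counts, in each CD106- library (n = 2), CD106+ library (n = 2) and the dexamethasone CD106+ library (n = 1), with bars at the group means. Pecam1 lies at 22.1 and 16.54 CPM in the untreated CD106+ libraries and at 508 CPM in the treated library.

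Among the individually profiled cells, those from dexamethasone-injected dams carried more matrix fibroblast and less endothelial RNA than those from saline controls, and less contractile RNA in sums that rest on few cells. Levels are sums over the cells of a group with exact Poisson intervals, which cover counting error only. Limch1 stood at 3919 CPM (3885 to 3953) against 1522 CPM (1502 to 1542), Vcam1 at 1127 CPM (1109 to 1145) against 299 CPM (291 to 308) and Fgf10 at 400.4 CPM (389.6 to 411) against 147 CPM (141 to 153), the dexamethasone value first, and 10 of 15 matrix fibroblast markers were 2-fold or more higher (median 1.31). Smooth muscle markers were at 0.5-fold or less in 11 of 12 cases (median -3.27), with Acta2 at 666 CPM (652 to 680.4) against 3145 CPM (3117 to 3174) and Tagln at 234 CPM (226 to 243) against 1720.3 CPM (1699 to 1742), and 1 cell in each group supplied 62.8% and 62.6% of the Acta2 reads of the dexamethasone and saline groups. In the saline group 1 cell held 63.0% of the Tagln reads. The medians over cells ran the other way, at 37.1 CPM under dexamethasone against 6.23 CPM for Acta2 and 38.4 against 1.18 CPM for Tagln, so the lower sums do not describe the typical cell. Endothelial markers were lower in 14 of 15 cases (median -3.52), with Pecam1 above 100 CPM in 1 of 15 dexamethasone and 5 of 11 saline cells, and 1 cell held 98.1% of the dexamethasone Pecam1 reads.

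Glucocorticoid targets did not stand above other genes in these cells, with a median log2 ratio of -0.62 over 29 genes, at percentile 4.56 of random matched lists. Tsc22d3 stood at 166 CPM (159 to 173) against 746 CPM (732 to 759.7), Fkbp5 at 53.6 CPM (49.8 to 57.8) against 139 CPM (133 to 145) and Errfi1 at 137 CPM (131 to 143) against 9.09 CPM (7.62 to 10.8), the last with 75.5% of its dexamethasone reads in 1 cell. In the saline group 1 cell held 87.2% of the Fkbp5 reads and 1 held 89.6% of the Errfi1 reads. Without the cells above 100 CPM of Pecam1 the target median was 0.27, an alternative chosen after seeing the data. Some of those cells held matrix fibroblast markers too, so their removal took out more than endothelial RNA. Immediate early genes had a median of -1.61. Haemoglobin genes gave the largest ratios, and 1 cell held 99.9% of the Hba-a1 reads of the dexamethasone group. Of 212 genes raised in sorted mesenchyme, 104 lay on the same side in these cells (49.1%, random lists 47.6%), as did 40 of 66 lowered genes (60.6%, random lists 51.5%). Both sets keep genes on X or Y. No animal is named for any cell, so each group counts as 1 sample and nothing was tested. The groups differed in depth, with medians of 852850 and 1349765 reads and 3435 and 5114 detected genes per cell for dexamethasone and saline. The labels of all dexamethasone cells begin with a prefix that no saline label carries, and a cell number with its index recurs in both groups. The groups may thus have been run separately, which cannot be told apart from treatment.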

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

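The tests of sex were written before their results were seen, and the tests of cartilage cells, of endothelial cells and of a response in mesenchyme, with the covariates, were chosen afterwards. In 107 sets of 4 dexamethasone mesenchyme values, 8 held a pool far from the other 3 by Dixon's criterion at 95%, where chance gives about 1 in 20. These were Fkbp5 at 264 CPM in pool 1 against 178 to 189.8, Pnpla2 at 46.7 CPM in pool 1 against 14.1 to 18.4, Cspg4 at 375 CPM in pool 1 against 169.7 to 201, Mcm5 at 9.13 CPM in pool 3 against 5.10 to 5.29, Tsc22d3 at 127 CPM in pool 3 against 173 to 174, Ptprc at 12.3 CPM in pool 3 against 0.344 to 1.44, Acta2 at 524 CPM in pool 4 against 545 to 549 and Bnc1 at 8.62 CPM in pool 4 against 1.38 to 1.83 CPM.

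The sex of the pooled pups differed between the treatments, and could in principle account for genes that dexamethasone raised or lowered in mesenchyme. Dexamethasone pool 2 held both sexes, with a female share of 0.423 from Xist and 0.558 from Y-linked genes, so genes set by sex should lie at that position between the other dexamethasone pools (0) and saline (1). The median position was 0.0625 (-0.0129 to 0.119) over 174 raised and 0.075 (0.00922 to 0.182) over 60 lowered autosomal genes called without that pool, which argues against sex as their main source, although it rests on 1 pool. With Xist as a covariate the median fold of raised genes went from 1.60 to 1.72 on the log2 scale and its SE from 0.29 to 0.64, and of lowered genes from -1.70 to -1.62 and from 0.36 to 0.92. Those genes had been called with pool 2 included, so the kept folds do not test sex. The calls ended because Xist was highest in both saline pools, so that the covariate nearly stands for treatment, and the errors grew, so treatment is a candidate explanation that this design tests only through pool 2.

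Cartilage cells in the saline sorts may account for part of the genes lowered by dexamethasone. A first test compared the saline pools, where lowered genes had a median log2 ratio of pool 1 to pool 2 of 0.0933 (-0.109 to 0.237) and chondrocyte markers 1.01 (0.123 to 1.55), and the intervals overlapped. A second, added because the first had decided nothing, placed dexamethasone pool 3 at 0.247 (0.145 to 0.331) between the other dexamethasone pools and saline over 104 lowered genes and at 0.467 (0.313 to 0.795) over the markers, and these intervals overlapped too. With the marker level as a covariate the median fold of lowered genes went from -1.70 to -1.52 and its SE from 0.36 to 0.61, leaving 1 call downwards. Cartilage cells and treatment cannot be told apart for the lowered genes, since the markers were themselves highest in both saline pools.

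Endothelial transcripts in the dexamethasone CD106+ library may come from endothelial cells. The labels describe a removal of cells that carry CD31 and CD309, the products of Pecam1 and Kdr, for the accessibility samples only, so it is not known whether this RNA library went through it. Of 15 markers, 11 of them also tested in the CD106 fractions, 100% were 4-fold or more above the untreated CD106+ libraries, with Pecam1 at 508 and Flt1 at 202 CPM, which restates the observation and decides nothing. A rise of these genes in mesenchymal cells was looked for in the sorted mesenchyme, where 10 of the markers had a median log2 fold change of -0.37 (-0.91 to 0.76) 2 hours after dexamethasone against 3.80 in this library. In the single cells taken 24 hours after injection the 15 markers had a median log2 ratio of -3.52 (-5.00 to -2.92). That ratio compares sums over cells, and 5 of 11 saline but 1 of 15 dexamethasone cells held Pecam1 above 100 CPM. It depends on how many cells with endothelial RNA were sampled, so it cannot show whether mesenchymal cells changed. Of the cells above 100 CPM of Pecam1, saline cells 6, 9 and 10 and dexamethasone cell 9 also held matrix fibroblast markers. Their list levels on a log2 scale were 8.45, 7.63, 8.34 and 9.26. Saline cells 1 and 7 stood at 4.43 and 2.04, and the saline median was 4.76. Whether such captures held more than 1 cell was not tested. The sorted mesenchyme at 2 hours showed no rise as large as that of this library. The labels' 2 hours for bulk RNA are given with the Twist2Cre sort and not for the CD106 libraries by name, and neither of the 2 sets was sorted for CD106, so the 2 explanations cannot be told apart. Immune genes, and erythroid genes with an interval that spans 0, had higher medians as well. An effect of treatment on which cells carried CD106 was not tested.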

How the results depend on the processing

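The covariates for Xist and chondrocyte markers and the removal of sex chromosome genes, Rn45s and Pecam1 cells, and of Vcam1 from its lists, were chosen after the results were seen. With the Xist and chondrocyte covariates, 0 and 44 mesenchyme genes passed. Both covariates were highest in both saline pools, and the errors grew. Under the chondrocyte covariate the median folds also shrank, from 1.60 to 1.37 for raised and from -1.70 to -1.52 for lowered genes. Its loss of calls therefore does not tell cartilage cells from treatment. The 306 genes changed in mesenchyme became 598 without a filter and 512 by DESeq2. They ranged from 179 to 335 with a pool left out, where a lone saline pool is assumed to vary like the dexamethasone pools. The 7 lists past the threshold ranged from 4 to 8 with a pool left out and became 1 with an estimated correlation and 3 by fry. The replicate number as a block left 154 genes, of which 114 were among the 306. Same-numbered pools had correlations across genes of their deviations of -0.05 and 0.05 (0.01 in the CD106 set). With 2 libraries in a group the deviations are exact opposites, so these values cannot show whether same-numbered samples were paired. The CD106 labels give each number to 1 positive and 1 negative library, so a shared preparation remains possible there. Under that block the epithelial list turned to a median of -3.63 (adjusted p = 2.9e-05), and the erythroid list ranged from -1.73 to 0.80 with a pool left out, turning without saline pool 1; the causes were not tested. The 1239 CD106 genes ranged from 546 to 2756 with a library left out, where the lone library is assumed to vary like the pair, and became 1276 under the block. Of the 17 CD106 lists, 0 passed with an estimated correlation and 0 by fry, and the NF-kB list lost its call without Vcam1, from a median of 0.57 to 0.48 (camera adjusted p = 0.23). Genes raised and lowered in mesenchyme lost their call between the CD106 fractions with an estimated correlation, at medians of 0.143 and 0.0195. The same-direction share in the dexamethasone CD106+ library was 68.3%, 71.0% with TMM factors, 71.1% by edgeR over 3 groups, and 66.3% to 68.0% with an untreated library left out; the cause was not tested. Keeping cells with 1000 or more genes removed none. Other scalings, limma-voom and a stricter filter gave 264 to 421 mesenchyme genes and, with no filter and DESeq2, 1123 to 1468 CD106 genes. For the dexamethasone CD106+ library an edgeR fit over 3 groups, which assumes that it varies like the replicated CD106 libraries, called 1842 of 13708 genes, 1012 higher and 830 lower, and was used only as an alternative. Of results for named genes under all settings, 199 in mesenchyme and 46 in the CD106 set lost the threshold, 73 and 39 gained it, and 0 turned with a call on either side. Some with no call on either side changed sign, as Vcam1 did in mesenchyme, from -0.39 to 0.92 with a pool left out. Over all genes, calls with the sign opposite to the main fit numbered 1 without CD106- library 2, 4 without CD106+ library 1, 1 without CD106+ library 2 and 0 under the other settings. At the size of the mesenchyme comparison simulated recovery of changes of 1 on the log2 scale was 14%, and what depth or the number of saline pools adds to that was not tested.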

Other observations

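Both tests here were chosen after the results for mesenchyme were seen, and the genes of the opening were picked by their values. Outside the fixed lists, dexamethasone raised and lowered further genes in sorted mesenchyme. Trp53inp1, a stress and autophagy regulator, stood at 465 ± 43.0 against 87.4 ± 2.35 CPM, the NAD synthesis enzyme gene Nampt at 536 ± 114 against 105 ± 0.632 CPM and Arrdc3, an arrestin family member, at 952 ± 74.0 against 211 ± 66.1 CPM (edgeR adjusted p = 1.7e-05, 4.5e-05 and 5.8e-05). The mTOR inhibitor Deptor rose by 2.41 on the log2 scale and the interleukin 6 receptor gene Il6ra by 2.23. Notch pathway genes Heyl and Jag1 fell, by 1.21 and 1.71, and the prostaglandin synthase gene Ptges fell by 2.15. The 5 rises kept their calls whichever pool was left out. Heyl lost its call without saline pool 1 (adjusted p = 0.082), Jag1 without saline pool 1 or dexamethasone pool 1 (adjusted p of 0.057 to 0.19) and Ptges without saline pool 1 or 2 (adjusted p of 0.094 to 0.1).

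Trp53inp1 may belong to a wider set of raised FoxO-regulated and autophagy genes, which stays undecided. A list of such genes, written after the leading changed genes had been seen and tested without the 6 members already seen or held in the target list, had a median log2 fold change of 0.67 (0.33 to 0.94) over 27 genes (camera p = 2.0e-08, 3.9e-08 adjusted over 2 lists). Of the 27, 5 rose at an edgeR adjusted p under 0.05, namely Foxo3 by 1.61, Gabarapl1 by 1.92, Txnip by 1.33, Cited2 by 1.27 and Sesn1 by 1.15, 0 fell, and 11 rose and 1 fell when adjusted over the list alone. With an estimated correlation p was 0.034 and 0.068 after adjustment, so the set call is lost there. Foxo3 kept its call whichever pool was left out. Gabarapl1 lost it without saline pool 1 or 2 or dexamethasone pool 1 (adjusted p of 0.058 to 0.11), Txnip without saline pool 2 (adjusted p = 0.14), Cited2 without saline pool 1 or 2 or dexamethasone pool 2 (adjusted p of 0.059 to 0.13) and Sesn1 without saline pool 2 or dexamethasone pool 1 or 4 (adjusted p of 0.052 to 0.18). Since the list was composed after the leading genes were known, the test does not decide the hypothesis. The difference in sex between the pools applies to this list too.

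A second hypothesis, that imprinted genes of the fetal growth network fell together, was not decided. Without 3 genes already seen, 15 genes had a median of -0.13 (-0.64 to 0.19), with p = 0.19 by camera and 0.32 with an estimated correlation. Nnat was the single gene to fall, by 1.36, a call lost without saline pool 2 or dexamethasone pool 1, 2, 3 or 4 (adjusted p of 0.052 to 0.36), and a fall of the set as large as the lower end of that interval could not be excluded.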
